A study of Homo sapiens with 14 samples.

How the data were processed

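Small RNA was sequenced from human pancreatic islets kept in culture for up to 28 days. Per the labels, 3 islet preparations were sampled on days 1, 7, 14 and 21, and 2 of them also on day 28, which gave 14 libraries. The preparations are called A, B and C here, and carry the replicate numbers 1, 2 and 3. Total RNA was extracted with Trizol, and libraries were made by a modified Illumina v1.5 small RNA protocol whose 5′ adaptor ends in 3 random nucleotides, per the labels' protocols.

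The deposited table holds 1 sheet of read counts and 1 sheet of RPM for 2743 miRNA entries, of which 1279 had reads in at least 1 library. CASAVA 1.8, cutadapt, DESeq2 and hg38 are named in the submitters' processing notes, with no role given. The aligner, the miRNA annotation release and the use made of the 3 random nucleotides are not given in the sources used here. In the deposited count sheet no value of 1 occurs (0 values of 1, beside 128 values of 2 and 28217 zeros), for which the labels give no reason. In the deposited RPM sheet, each value equals the authors' count, with 0 replaced by 1, scaled by the column sum after that replacement. Dividing each RPM column by its smallest value gave whole reads for 100% of the values (tolerance 1e-06), and 100% of them equalled the counts with 0 read as 1. The counts were therefore the values tested, and the RPM served in alternatives. Every column of both sheets was matched to 1 sample by its title. An entry whose name joins miRNAs with a slash (62 entries) holds reads of near-identical mature sequences, and its change cannot be assigned to 1 of them.

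Differences between days were tested with edgeR 4.0.16 in R 4.3.3. All 14 libraries entered 1 fit with 5 day groups, so that the groups shared 1 estimate of spread. miRNAs were kept by filterByExpr with the day as group (minimum count 10, minimum total 15), which left 783, and these held at least 99.988% of the reads of every library. Libraries were scaled by TMM, dispersion was fitted with glmQLFit and robust set to true, and quasi-likelihood F tests were adjusted by the Benjamini-Hochberg method at 0.05. Adjusted p-values without another tool named are from this test. Standard errors were taken from the log2 fold change and its F statistic. Normalised CPM is CPM on the TMM-scaled library size, so it can exceed a miRNA's share of reads where the scaling factor is below 1. The comparisons were each later day against day 1, any difference among the 5 days, day 14 against day 7, day 21 against day 7, day 21 against day 14, and day 28 against day 21. Labels record no library batch, so a batch that followed the day would be indistinguishable from it. Because the libraries of 1 day came from different islet preparations, p-values of this fit measure the spread between the preparations. This fit treats the 14 libraries as independent and leaves out that the same preparations recur on each day.

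The sample titles give the same preparation code on every day, so the libraries are paired by the labels. As a check, the correlation of deviations from the day means had a median of 0.391 among libraries of preparation A, 0.375 for B and 0.171 for C, where 1 pair of libraries reached -0.127, against -0.173 between different preparations. The blocked fit adds preparation as a term to the same edgeR model. Its p-values measure the spread left after steady differences between preparations are removed. Its value is given beside a count that it moved by more than 1.5 times, and beside many of the single miRNAs and lists whose call it changed.

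The design, the tests, the lists, the rule for named miRNAs and most alternatives were set before the data were examined. The 22 lists were pancreatic endocrine, the imprinted 14q32 cluster, acinar, miR-200 family, gastrointestinal and hepatic epithelial, other epithelial, mesenchymal, endothelial, leukocyte, red blood cell, muscle, NF-kB induced inflammation, hypoxia, miR-17/92 clusters, let-7, miR-29, miR-30, miR-21, miR-34, miR-132 and miR-212, miR-221 and miR-222, and pluripotency miRNAs. Lists with at least 3 tested members (15 lists) were tested with camera from limma 3.58.1 on edgeR log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of 1 comparison. The same test with an estimated correlation, and fry, were alternatives. Members of 1 list can share a hairpin, such as miR-126-3p and miR-126-5p, or a host gene. Examples are miR-216a-5p and miR-217-5p in MIR217HG, and miR-143-3p and miR-145-5p in CARMN. Such members are not independent, so p-values with the preset correlation can be too small, and counts of members are not counts of separate events. Counts of list members are given over all 783 miRNAs and adjusted over the list alone. miR-155-5p is in both the leukocyte and the inflammation list. Islets and other pancreatic cells also express many listed miRNAs at lower levels, so the lists are enriched in a cell type and are not exclusive to it.

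The named miRNAs were those picked by a fixed rule for each comparison against day 1 and for day 21 against day 7. It took the 6 largest rises and 6 largest falls past the threshold with a mean CPM of at least 10 and the same sign in every preparation. Where fewer than 10 miRNAs passed, as for day 7 against day 1 and day 21 against day 7, they came from the blocked fit. It also took up to 4 members of each list, called ones first and then the most abundant, and the 10 most abundant miRNAs. Those named outside the rule are said to be chosen after their values were seen.

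The alternatives set in advance were RLE scaling, library size only, no filter, a stricter filter (CPM of at least 10 in 3 samples), DESeq2 1.42.0, limma on log2(RPM + 1), a fit with only the 2 groups compared, the blocked fit, and leaving out each library in turn. Added after seeing the data were zeros read as 1 count, removal of miR-375-3p, removal of preparation A with and without the block, and the block with RLE scaling or with library size only. Against TMM, library size only moved the median of all miRNAs by -0.49 at day 7 against day 1, -0.69 at day 14, -0.67 at day 21 and -0.75 at day 28, and by -0.19 at day 21 against day 7 and -0.22 at day 14 against day 7. RLE moved it by -0.10 at day 7 against day 1. Changes are reported relative to the TMM scale.

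Where every library of a group had 0 reads, the fold was bounded with a floor of 3 counts per library, and a list's median is also given with such members at their bound. Depth ran from 6820050 to 16031415 reads, so 3 counts were worth 0.187 to 0.440 CPM. Shares of reads in 1 library carry Wilson 95% confidence intervals. Reads are not independent molecules, so intervals and floors cover counting error only. No pair of libraries of the same day agreed within sampling noise (chi-square per degree of freedom 316.1 to 8285). Hairpin positions are from GENCODE v29 on GRCh38, the build the processing notes name as hg38, and hairpin GC is from that genome. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

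The procedures were tested on simulated data, with 200 miRNAs changed by known folds on the real means and library sizes. Simulated libraries were drawn independently, with the spread of the unblocked fit and no effect of preparation. The recoveries therefore do not describe the blocked fit on paired libraries. For day 28 against day 1, simulated on 686 miRNAs, edgeR recovered 3.57% of those changed 2-fold, 28.3% of those changed 4-fold and 66.1% of those changed 16-fold, and called 4 of 511 unchanged ones. The corresponding recoveries were 5.26%, 42.6% and 66.7% for day 7 on 701 miRNAs, 10.5%, 34.9% and 61.1% for day 14 on 685, 8.47%, 32.8% and 65.0% for day 21 on 698, and 3.28%, 33.9% and 62.3% for day 21 against day 7 on 707. In these simulations without pairing, a change of 2-fold or 4-fold mostly went uncalled by the unblocked fit at this number of samples.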

Results

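Mature miRNAs were counted by small RNA sequencing in human pancreatic islets held in long-term culture. Islets are the endocrine clusters of the pancreas, and isolated preparations also carry acinar, ductal, stromal, endothelial and blood cells. The 14 libraries formed 5 groups by day of culture: day 1, day 7, day 14 and day 21 with 3 libraries each (preparations A, B and C), and day 28 with 2 (A and B). Preparation A had 6820050, 8064974, 10710634, 7552323 and 11762343 reads on miRNAs on days 1, 7, 14, 21 and 28. Preparation B had 11764079, 13837069, 14192910, 14154924 and 13126425 on the same days, and preparation C had 14916300, 16031415, 12599210 and 15791956 up to day 21. Between 680 and 806 miRNAs were detected per library, and 783 were tested.

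A single miRNA, miR-375-3p, the most abundant miRNA of endocrine islet cells, made up a large part of the reads on every day. It comes from MIR375, an intergenic hairpin on chromosome 2 (219001645 to 219001708, GRCh38). Its share of reads was 34.2% ± 18.0 (SD, n = 3) on day 1, 58.1% ± 13.3 (n = 3) on day 7, 61.7% ± 5.26 (n = 3) on day 14, 66.1% ± 12.3 (n = 3) on day 21 and 69.5% ± 13.2 (n = 2) on day 28. Single libraries ran from 14.85% in preparation A on day 1 (Wilson 95% interval 14.83% to 14.88%) to 78.84% in preparation B on day 28 (78.82% to 78.86%). miR-7-5p, an endocrine miRNA with 3 hairpin genes, held 12.5% ± 9.35 (SD, n = 3) of reads on day 1 and 4.35% ± 4.39 (n = 2) on day 28. miR-148a-3p, abundant in acinar cells, held 9.96% ± 5.11 on day 1 and 0.720% ± 0.548 on day 28. miR-143-3p, a miRNA of smooth muscle and fibroblasts, held 2.46% ± 0.721 of reads on day 1, 0.302% ± 0.0438 on day 7 and 0.00802% ± 0.00161 on day 28. Because shares within a library sum to a whole, the tests below used TMM-scaled counts. The day 1 library of preparation A lay farthest from the others (-42.17 on a first principal component holding 31.3% of the variance).

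**Figure D1:**
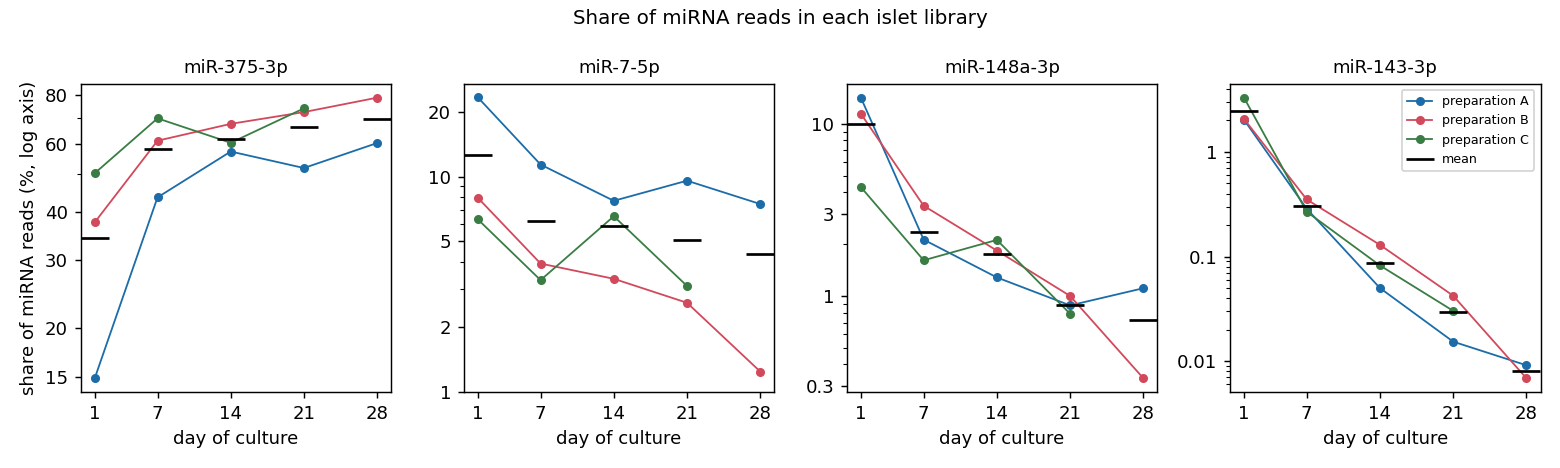
Share of reads (percent, log axis) of miR-375-3p, miR-7-5p, miR-148a-3p and miR-143-3p against day of culture, with 1 line per preparation and a black bar for the mean of each day. The mean share of miR-375-3p was 34.2% on day 1 and 69.5% on day 28, and that of miR-143-3p was 2.46% and 0.00802%.

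The first comparison asked what had changed after 1 week of culture. At day 7 against day 1, miRNAs of mesenchymal cells (fibroblasts, stellate cells and smooth muscle) fell. miR-145-5p, from MIR145 on chromosome 5 (149430646 to 149430733) in an intron of the long non-coding RNA gene CARMN, changed by -2.81 ± 0.42 log2 units (SE, 3 libraries per day, adjusted p = 0.0121) and was lower in all 3 preparations. Its normalised CPM was 35.3 ± 15.6 at day 7 and 247 ± 61.9 at day 1. miR-199a-5p, encoded at a locus on chromosome 1 and another on chromosome 19, changed by -2.60 ± 0.52 (adjusted p = 0.0481) and miR-199b-5p by -2.75 ± 0.53 (adjusted p = 0.0481), both lower in all 3 preparations. Of the 10 mesenchymal members, 3 fell, and 9 adjusted over the list alone. Their median change was -2.50 (camera, adjusted p = 2.6e-13 with the preset and 0.000825 with an estimated correlation).

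With preparation as a block, 7 mesenchymal members fell at day 7, among them miR-143-3p, which changed by -2.49 ± 0.46 (adjusted p = 0.0122). The endothelial miRNAs miR-126-3p and miR-126-5p, both from MIR126 in an intron of EGFL7 (chromosome 9, 136670602 to 136670686), fell in the blocked fit by 3.37 ± 0.30 (adjusted p = 5.03e-05) and 3.35 ± 0.35 (adjusted p = 0.000139), in all 3 preparations. Without the block their adjusted p were 0.144 and 0.220. As a list, the 4 endothelial miRNAs had a median of -1.99 (camera, adjusted p = 0.0126, and adjusted p = 0.0862 with an estimated correlation), with 2 members lower adjusted over the list alone. The list of 7 acinar miRNAs fell (median -1.44, adjusted p = 7.42e-06, and adjusted p = 0.109 with an estimated correlation). None of its members was called without the block (edgeR), 5 fell adjusted over the list alone, and 3 fell in the blocked fit, including miR-217-5p by 2.70 ± 0.58 (adjusted p = 0.0302). The leukocyte list (median -2.81, adjusted p = 0.00129, and adjusted p = 0.0560 with an estimated correlation) and the miR-17/92 list of proliferation-linked clusters (median -1.37, adjusted p = 0.000227, and adjusted p = 0.116 with an estimated correlation) also fell. No member of either was called over all miRNAs (edgeR), while adjusted over the list alone 3 miR-17/92 members and 0 leukocyte members fell. miR-375-3p was at 1.43 ± 0.72 (adjusted p = 0.481, and 0.0561 with the block).

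In total 4 miRNAs were called at day 7, 1 higher and 3 lower. The higher one was miR-551b-5p, from MIR551B in an intron of EGFEM1P, at 2.10 ± 0.42 (adjusted p = 0.0481, higher in all 3 preparations, chosen after its values were seen). With the block 23 were called, 8 higher and 15 lower. Rises by the naming rule in the blocked fit were miR-877-5p (1.83, adjusted p = 0.0428), miR-342-3p (1.56, adjusted p = 0.0448), miR-873-3p (1.43, adjusted p = 0.0483) and miR-501-5p (1.26, adjusted p = 0.0259), each in all 3 preparations. None of the 4 was called with the block and library size only (1.24, 0.98, 0.83 and 0.64, adjusted p = 0.0519, 0.0799, 0.171 and 0.368) or with the block and without preparation A (adjusted p = 0.0851 to 0.155), and with RLE only miR-501-5p was. miR-143-3p and miR-217-5p were not called with the block and without preparation A either (adjusted p = 0.0851 and 0.164). The blocked list test added the endocrine list, whose median was 0.48 (adjusted p = 0.0340, and adjusted p = 0.216 with an estimated correlation), as well as 3 others, 14q32, miR-30, and miR-221 and miR-222 (adjusted p = 0.0340, 0.0160 and 0.0221, and adjusted p = 0.335, 0.216 and 0.216 with an estimated correlation). The split of calls turned further toward falls with other scalings: 0 higher and 3 lower with RLE and with library size only, and with the block 3 higher and 15 lower (RLE) or 1 higher and 35 lower (library size only). Leaving out 1 library gave 0 calls without day 7 of B or C (edgeR, 50 and 48 unadjusted), 1 without day 1 of A or C and 2 without day 7 of A or day 1 of B. With the block the counts were 10, 14 and 47 without day 1 of A, B and C, and 14, 9 and 8 without day 7. miR-145-5p was called in all but the first pair without the block (adjusted p = 0.110 and 0.0604), and with library size only or only the 2 groups it was not (adjusted p = 0.0969 and 0.0764). The call of miR-199a-5p ended without any of the 6 libraries (adjusted p = 0.0634 to 0.286), and that of miR-199b-5p without any but day 1 of B (adjusted p = 0.0557 to 0.286). Both also ended with library size only (adjusted p = 0.206 and 0.181), with only the 2 groups (adjusted p = 0.0764 and 0.181) and without miR-375-3p (adjusted p = 0.0509 and 0.0501), and that of miR-199b-5p without preparation A (adjusted p = 0.0772).

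Day 14 against day 1 asked the same after 2 weeks. Of the 10 mesenchymal members 7 fell, and all 10 adjusted over the list alone (median -4.18, or -4.02 with a member at 0 reads set to its bound, camera adjusted p = 1.43e-17 and 0.000255 with an estimated correlation). miR-145-5p changed by -4.57 ± 0.46 (adjusted p = 0.000139), miR-199a-5p by -4.64 ± 0.57 (adjusted p = 0.000743) and miR-143-3p by -4.05 ± 0.79 (adjusted p = 0.0167), each lower in all 3 preparations. miR-126-3p fell by 3.74 ± 0.84 (adjusted p = 0.0322) and miR-126-5p by 3.94 ± 0.95 (adjusted p = 0.0471), and the other 2 endothelial members were not called (list median -2.24, adjusted p = 0.0329, and adjusted p = 0.106 with an estimated correlation). miR-802, a miRNA of liver and pancreatic epithelium whose hairpin on chromosome 21 (35720715 to 35720808) lies opposite an intron of RUNX1, changed by -5.57 ± 1.23 (adjusted p = 0.0342), from 27.8 ± 26.1 to 0.586 ± 0.371 normalised CPM. miR-551b-5p rose by 2.42 ± 0.42 (adjusted p = 0.00732, all 3 preparations).

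Among other lists at day 14, the acinar list fell (median -1.80, adjusted p = 2.25e-05, and adjusted p = 0.106 with an estimated correlation), with 5 members lower adjusted over the list alone and 5 in the blocked fit, miR-148a-3p among them at -1.75 ± 0.47 (adjusted p = 0.0329). The leukocyte list fell (median -4.83, or -3.99 with members at their bound, adjusted p = 2e-04, and adjusted p = 0.0279 with an estimated correlation, or 0.219 with the block), with 4 members lower adjusted over the list alone and 5 in the blocked fit. That fit called miR-155-5p lower by 3.08 ± 0.53 (adjusted p = 0.00432) and miR-342-3p higher by 1.70 ± 0.39 (adjusted p = 0.0156), the latter not with library size only as well (0.95, adjusted p = 0.0745) or without preparation A (adjusted p = 0.228). The miR-17/92 list fell (median -1.84, adjusted p = 0.000142, and adjusted p = 0.106 with an estimated correlation), with miR-20a-5p at -2.52 ± 0.54 (adjusted p = 0.0291) as the called member (-1.50, adjusted p = 0.137, without preparation A) and 6 adjusted over the list alone. The 46 tested miRNAs of the imprinted 14q32 cluster had a median of -0.46 (adjusted p = 0.0329, and adjusted p = 0.447 with an estimated correlation). Of these, miR-487a-3p fell by 1.86 ± 0.41 (adjusted p = 0.0322), and 6 fell adjusted over the list alone. In the blocked fit, the endocrine miRNAs miR-375-3p, miR-182-5p and miR-183-5p rose by 1.79 ± 0.39, 1.49 ± 0.34 and 1.36 ± 0.31 (adjusted p = 0.0142, 0.0156 and 0.0156), each higher in all 3 preparations. Without the block their adjusted p were 0.355, 0.308 and 0.334. The blocked list test also called miR-30, and miR-221 and miR-222 (adjusted p = 0.0192 and 0.0179, and adjusted p = 0.262 and 0.260 with an estimated correlation).

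At day 14 19 miRNAs were called, 2 higher and 17 lower, and 79 with the block, 26 higher and 53 lower. The other higher one was miR-1908-5p at 2.97 ± 0.68 (adjusted p = 0.0361, chosen after its values were seen). With the block and library size only, the split was 4 higher and 76 lower, and miR-182-5p and miR-183-5p were no longer called (adjusted p = 0.0952 and 0.208), while miR-375-3p was at 0.98 (adjusted p = 0.0453). With the block and without preparation A none of these 3 endocrine miRNAs was called (adjusted p = 0.0565 to 0.194). Without the day 14 library of preparation A, B or C, 7, 9 and 8 were called, and with the block 25, 27 and 88, or 43 and 51 without day 1 of A and B. miR-145-5p and miR-199a-5p stayed among them, and miR-126-3p (adjusted p = 0.0518, 0.132 and 0.125) and miR-802 (adjusted p = 0.118, 0.106 and 0.125, and 0.0814 at -4.66 without day 1 of A) did not, nor did miR-126-5p, miR-20a-5p and miR-487a-3p (adjusted p = 0.0717 to 0.182). miR-143-3p was not called without day 14 of A or C (adjusted p = 0.0586 and 0.0926). miR-551b-5p was not called without day 14 of A (adjusted p = 0.0577), nor with library size only, limma or only the 2 groups (adjusted p = 0.206, 0.140 and 0.0625).

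Day 21 against day 1 compared the last day with all 3 preparations. The mesenchymal miRNAs were lower again: 9 of 10 fell, 10 adjusted over the list alone (median -5.38, or -4.89 at bound, camera adjusted p = 2.82e-19 and 0.00017 with an estimated correlation). miR-199a-5p changed by -6.23 ± 0.62 (adjusted p = 4.32e-05) and miR-214-3p, from MIR214 in an exon of DNM3OS, by -4.99 ± 0.50 (adjusted p = 4.32e-05). miR-143-3p changed by -5.42 ± 0.85 (adjusted p = 0.00261), from 17850 ± 9560 to 416 ± 310 normalised CPM. All of these were lower in all 3 preparations. miR-126-3p fell by 4.02 ± 0.85 (adjusted p = 0.0184), and the endothelial list had a median of -1.97 (camera, adjusted p = 0.119, and 0.0349 with the block, where adjusted p = 0.311 with an estimated correlation). With fry that list was called lower (adjusted p = 0.00394).

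Acinar miRNAs were also called singly at day 21: 4 of 7 fell, 5 adjusted over the list alone and 5 in the blocked fit (median -2.49, adjusted p = 2.27e-05, and adjusted p = 0.144 with an estimated correlation). Without preparation A none of the 4 was called (edgeR, adjusted p = 0.0512 to 0.200). Against their own day 1, the list medians of A, B and C were -3.69, -2.28 and -0.98. miR-148a-3p changed by -2.49 ± 0.57 (adjusted p = 0.0256), from 63400 ± 23400 to 11260 ± 5700 normalised CPM, and miR-217-5p, in an intron of MIR217HG, by -2.80 ± 0.67 (adjusted p = 0.0318). The leukocyte miRNA miR-142-5p had 0 reads in all 3 day 21 libraries and was at least 52.4-fold lower than at day 1 (adjusted p = 0.0104), or at least 30.5-fold without day 1 of A, and without preparation A it was not called (adjusted p = 0.0547). The leukocyte list fell (median -7.11, or -4.06 at bound, adjusted p = 0.00023, and adjusted p = 0.0293 with an estimated correlation, or 0.265 with the block), with 4 members lower adjusted over the list alone and 5 in the blocked fit. The miR-17/92 list fell too (median -2.01, adjusted p = 0.000217, and adjusted p = 0.144 with an estimated correlation), with 2 members called and 7 adjusted over the list alone. Neither of the 2 was called without preparation A (edgeR, adjusted p = 0.0633 and 0.241). The list medians of A, B and C against their own day 1 were -2.14, -1.37 and -0.595. miR-30a-5p, of a family described in the mesenchymal transition of islet cells, changed by -3.66 ± 0.90 (adjusted p = 0.0363), from 1313 ± 1650 to 104 ± 41.0 normalised CPM. Without the day 1 library of preparation A it was at -1.95 (adjusted p = 0.126), and without the day 21 library of A, B or C it was not called either (adjusted p = 0.0903, 0.106 and 0.125). In the blocked fit miR-375-3p rose by 1.83 ± 0.38 (adjusted p = 0.00821), miR-182-5p by 1.47 ± 0.34 and miR-183-5p by 1.34 ± 0.31 (both adjusted p = 0.0135), in all 3 preparations, while the endocrine list of 11 had a median of 0.39 (adjusted p = 0.397). With the block and library size only miR-375-3p was at 1.04 (adjusted p = 0.0216), and miR-182-5p and miR-183-5p were not called (0.71 and 0.56, adjusted p = 0.0829 and 0.255), the former also not with the block and without preparation A (adjusted p = 0.0518).

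The calls at day 21 numbered 33, 3 higher and 30 lower, and 104 with the block, 35 higher and 69 lower, or 5 higher and 117 lower with the block and library size only. The 3 higher ones, chosen after their values were seen, were miR-551b-5p (2.17, adjusted p = 0.0104), miR-1908-5p (2.89, adjusted p = 0.0297) and miR-483-5p (2.23, adjusted p = 0.0390). With the block the 14q32, NF-kB induced and miR-30 lists were also called (adjusted p = 0.0375, 0.0470 and 0.0416, and adjusted p = 0.311 for each with an estimated correlation). Without the day 1 or day 21 library of preparation A, or the day 21 library of C, 21, 15 and 19 miRNAs were called, and with the block 63, 56 and 64, or 57 and 51 without day 1 or day 21 of B. miR-148a-3p was not called without day 21 of A or C or day 1 of B (adjusted p = 0.0658, 0.0521 and 0.0673), miR-217-5p without either library of A or B (0.0503 to 0.128), and miR-126-3p without day 21 of B or C (0.0811 and 0.0723). Without preparation A as a whole, miR-217-5p was at -2.07 (edgeR, adjusted p = 0.200, and 0.0681 with the block).

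The longest interval, day 28 against day 1, rested on 2 libraries (preparations A and B) against 3. Mesenchymal miRNAs showed the largest falls among called miRNAs with reads on both days. miR-143-3p, from MIR143 in an exon of CARMN (chromosome 5, 149428918 to 149429023), changed by -7.49 ± 1.13 log2 units (adjusted p = 0.00175), from 17850 ± 9560 (SD, n = 3) to 99.2 ± 28.3 (n = 2) normalised CPM. miR-199a-5p changed by -7.25 ± 0.78 (adjusted p = 0.000112), miR-145-5p by -6.69 ± 0.61 (adjusted p = 5.03e-05) and miR-10b-5p by -5.81 ± 1.02 (adjusted p = 0.00651). Each was lower in both preparations. Of the 10 members 9 fell, also adjusted over the list alone (median -6.68, or -5.995 with the 2 members at 0 reads set to their bound, camera adjusted p = 7.06e-18 and 0.000236 with an estimated correlation).

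Some miRNAs of other cell types were lower as well at day 28. Of the 7 acinar miRNAs 5 fell, and 6 adjusted over the list alone (median -3.07, adjusted p = 2.38e-06, and adjusted p = 0.119 with an estimated correlation). miR-217-5p changed by -3.81 ± 0.83 (adjusted p = 0.0239) and miR-148a-3p, from the intergenic MIR148A on chromosome 7 (25949919 to 25949986), by -3.05 ± 0.69 (adjusted p = 0.0249). With only the 2 groups neither of these was called (edgeR, adjusted p = 0.0739 and 0.0662). miR-217-5p was also not called without preparation A (-3.90) or without day 28 of B (-3.26). miR-126-3p fell by 4.04 ± 1.01 and miR-126-5p by 4.70 ± 1.18 (both adjusted p = 0.0390). The other endothelial members were not called, miR-139-5p at 0.03 ± 0.57 and miR-139-3p at 1.84 ± 1.33, which become -1.02 and -0.12 with the block and library size only. The list was not called by camera (median -2.01, adjusted p = 0.205), while fry called it lower (adjusted p = 0.00374). The leukocyte list fell (median -7.43, or -3.995 with 3 members at their bound, adjusted p = 0.00252, and adjusted p = 0.0736 with an estimated correlation). No member was called over all miRNAs (edgeR), and 4 fell adjusted over the list alone and 4 in the blocked fit, such as miR-155-5p by 4.52 ± 0.69 (adjusted p = 0.00157). miR-802 had 0 reads at day 28 and was at least 90.2-fold lower (adjusted p = 0.0156), or at least 43.5-fold without day 1 of A. It was not called without day 28 of B (adjusted p = 0.0836) or without preparation A (adjusted p = 0.0622).

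Proliferation-linked miR-17/92 miRNAs fell as a list of 12 (median -2.19, adjusted p = 0.000532, and adjusted p = 0.178 with an estimated correlation), with 2 called, 7 adjusted over the list alone and 6 in the blocked fit. Examples were miR-20a-5p at -3.67 ± 0.67 (adjusted p = 0.00821) and the joined entry miR-106a-5p/17-5p, which cannot be parted, at -2.51 ± 0.57 (adjusted p = 0.0249). With only the 2 groups neither was called (edgeR, adjusted p = 0.0804 and 0.156). The joined entry was not called with library size only either (adjusted p = 0.0632). Nor was it called without preparation A (-1.715), without day 28 of A (-2.58) or without day 28 of B (-2.44). Of 46 tested 14q32 miRNAs, 1 fell over all miRNAs, 0 adjusted over the list alone (edgeR) and 11 in the blocked fit (median -0.63, adjusted p = 0.0140, and adjusted p = 0.364 with an estimated correlation). The called one, miR-487a-3p, changed by -1.86 ± 0.48 (adjusted p = 0.0410). It was not called with library size only, no filter, limma or only the 2 groups (adjusted p = 0.234, 0.0878, 0.0509 and 0.261). Nor was it without day 1 of A, B or C (edgeR, adjusted p = 0.0713 to 0.0762), and it was at -1.35 without day 28 of B. In the list of other epithelial miRNAs, miR-31-5p fell by 4.16 ± 0.95 (adjusted p = 0.0254), and miR-203a-3p was at -2.13 ± 0.70 (adjusted p = 0.124, and 0.00440 with the block). Both fell adjusted over that list alone. The call of miR-31-5p ended with only the 2 groups and without day 1 of C (edgeR, adjusted p = 0.0662 and 0.0553). It also ended in the fits that left 1 library at day 28. These were without preparation A (-4.27), without day 28 of A (-4.38) and without day 28 of B (-4.05).

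The 11 tested endocrine miRNAs had a median change of 0.39 at day 28 (camera, adjusted p = 0.362), and none was called without the block (edgeR). With the block 3 rose: miR-375-3p by 2.30 ± 0.43 (adjusted p = 0.00440, 0.227 without the block), miR-182-5p by 1.66 ± 0.38 (adjusted p = 0.0112, 0.235) and miR-183-5p by 1.59 ± 0.35 (adjusted p = 0.00917, 0.294). With the block and library size only, miR-375-3p was at 1.27 (adjusted p = 0.0128), and miR-182-5p and miR-183-5p were not called (0.68 and 0.61, adjusted p = 0.127 and 0.256). miR-7-5p was at -0.83 ± 0.48 (adjusted p = 0.352). It was called lower in the block with library size only (-1.95, adjusted p = 0.00455) and with RLE (-0.95, adjusted p = 0.0494).

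Several of the remaining lists had blocked calls at day 28. In the blocked fit 3 of 8 miR-200 family members fell, miR-200a-3p by 1.47 (adjusted p = 0.0342) among them, and 3 of 6 miR-30 members, with miR-30a-5p at -3.77 ± 0.83 (adjusted p = 0.00951). Also lower there were 2 of 3 miR-29 members, 2 of 6 NF-kB induced miRNAs, with miR-146b-5p (adjusted p = 0.0216) and miR-155-5p, miR-34a-5p (adjusted p = 0.0262) of 2 miR-34 miRNAs, and miR-451a (adjusted p = 0.0361) of 2 red blood cell miRNAs. Higher there were miR-342-3p by 2.25 ± 0.43 (adjusted p = 0.00451), miR-221-5p by 1.37 (adjusted p = 0.0112) of the 4 from miR-221 and miR-222, and the joined miR-133a-3p/133b by 1.31 (adjusted p = 0.0454) of 2 muscle entries. With library size only as well, miR-342-3p alone of these 3 was called (1.26, adjusted p = 0.0218). With the block and without preparation A, miR-451a and the joined miR-133a-3p/133b were not called (adjusted p = 0.357 and 0.174). None of these members was called without the block (edgeR), though 1 miR-30 member and miR-451a fell adjusted over their list alone.

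The medians of these lists at day 28, with camera's adjusted p, were -0.81 for miR-200 (0.338), -0.84 for miR-30 (0.165, and 0.0477 with the block, where adjusted p = 0.328 with an estimated correlation), -0.95 for miR-29 (0.362), -1.18 for NF-kB induced miRNAs (0.265) and 0.44 for miR-221 and miR-222 (0.294). Lists without any call by edgeR or camera in either fit were gastrointestinal and hepatic epithelial (3 members, median -0.76, adjusted p = 0.263), let-7 (8 members, 0.11, adjusted p = 0.421) and miR-132 and miR-212 (4 members, 0.69, adjusted p = 0.362). By fry the first of these was called lower (adjusted p = 0.0245), as were the miR-30 and NF-kB induced lists (both adjusted p = 0.0283). Lists too short to test had medians of -3.14 (other epithelial), -2.06 (red blood cell), 0.71 (muscle), -2.05 (miR-34) and -2.83 (miR-21), and the hypoxia miRNA miR-210-3p was at -0.81 ± 0.79 (adjusted p = 0.609). None of the 8 pluripotency miRNAs had enough reads to be tested.

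Rises at day 28 were fewer. By the naming rule they were miR-551b-5p at 2.63 ± 0.45 (adjusted p = 0.00541), miR-423-5p, in an exon of NSRP1, at 2.48 ± 0.60 (adjusted p = 0.0346), miR-1275 at 1.86 ± 0.49 (adjusted p = 0.0469) and miR-455-3p, in an intron of COL27A1, at 1.59 ± 0.40 (adjusted p = 0.0410), each higher in both preparations. With library size only none of these 4 was called (adjusted p = 0.234, 0.315, 0.519 and 0.519), though each stayed above 0. In total 35 miRNAs were called at day 28, 8 higher and 27 lower, and 118 with the block, 36 higher and 82 lower. With library size only the splits were 1 higher and 29 lower without the block and 8 higher and 163 lower with it. Without the day 28 library of preparation B, 8 were called, 0 of them higher, and 47 with the block, which called 73 without day 1 of A. Without day 28 of B, miR-423-5p and miR-1275 were at 1.27 and 1.19 (both adjusted p = 0.655), and miR-551b-5p and miR-455-3p at 2.40 and 1.48 (adjusted p = 0.0719 and 0.331). Of the miRNAs named above as called, miR-143-3p, miR-145-5p and miR-199a-5p were still called without that library, while for instance miR-10b-5p, miR-126-3p and miR-148a-3p were not (adjusted p = 0.0719, 0.354 and 0.207). Other single libraries also ended some calls, such as that of miR-126-3p without day 1 or day 28 of A (adjusted p = 0.0834 and 0.0643) and of miR-148a-3p without day 1 of B (adjusted p = 0.0609).

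**Figure D2:**
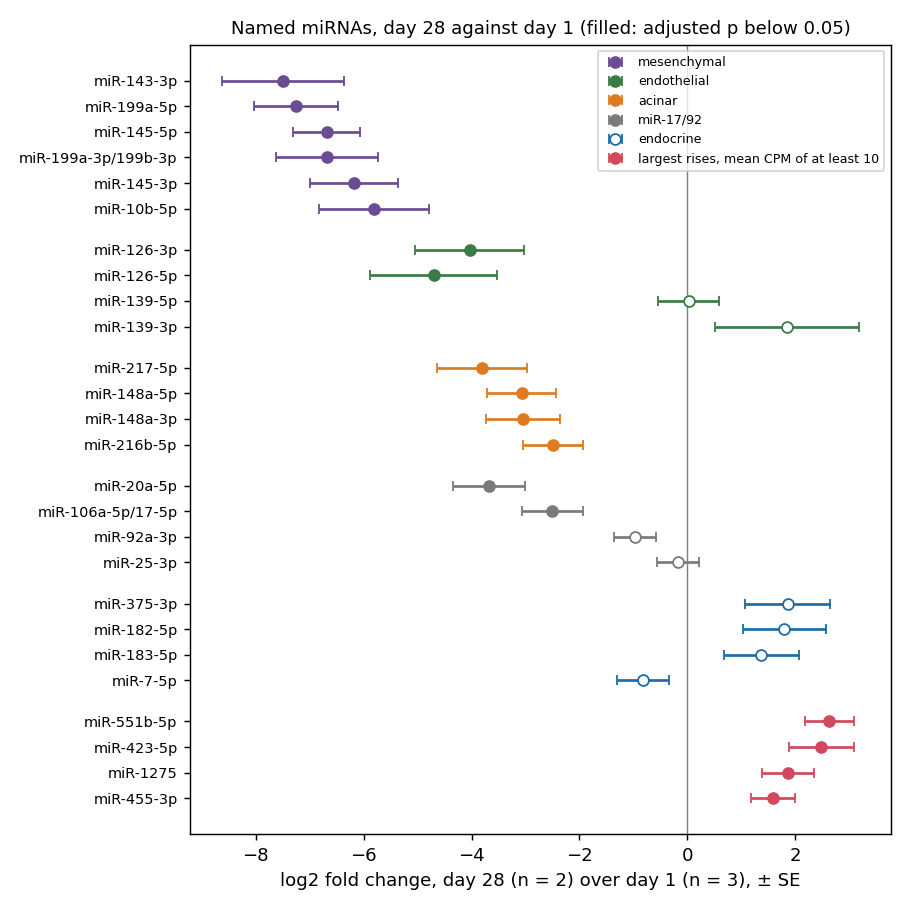
Log2 fold change at day 28 against day 1 (x axis, bars are 1 SE; 2 against 3 libraries) of miRNAs named by the fixed rule, grouped by list, with filled points for an adjusted p below 0.05 in edgeR. Mesenchymal miRNAs lie from -7.49 to -5.81, while no endocrine miRNA is filled, with miR-375-3p at 1.86.

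Comparisons that leave out day 1 asked whether change went on later in culture. From day 7 to day 21, 3 miRNAs fell, all mesenchymal: miR-199a-5p by 3.63 ± 0.55 and miR-214-3p by 3.21 ± 0.46 (both adjusted p = 0.00660), and miR-145-5p by 2.64 ± 0.42 (adjusted p = 0.00795), each in all 3 preparations. The mesenchymal list fell (median -2.87, or -2.71 at bound, camera adjusted p = 5.87e-23 and 7.84e-05 with an estimated correlation), with 9 members lower adjusted over the list alone. With the block 8 miRNAs fell, 7 of them in this list, including miR-143-3p by 3.21 ± 0.47 (adjusted p = 0.00297, and 0.0601 without preparation A). The leukocyte list fell as well (median -3.55, or -2.93 at bound, adjusted p = 0.0179, and adjusted p = 0.130 with an estimated correlation), with 1 member lower adjusted over the list alone. With library size only the 3 miRNAs were not called (adjusted p = 0.0919 to 0.113). miR-145-5p was not called without preparation A (-1.94, adjusted p = 0.0650, and 0.0601 with the block), with limma (0.112) or with only the 2 groups (0.149), nor was miR-214-3p with the latter pair (0.0507 and 0.0523). Without the day 21 library of preparation C 0 miRNAs were called by edgeR (30 unadjusted), with adjusted p = 0.0504 for each of the 3 named, and without the day 7 library of preparation A 5 were.

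Neighbouring days differed little in calls. From day 7 to day 14 edgeR called 0 miRNAs (20 at an unadjusted p below 0.05, DESeq2 2, limma 0), and 1 with the block, the joined entry of miR-199a-3p and miR-199b-3p at -1.87 ± 0.27 (adjusted p = 0.0111, chosen after its values were seen). That blocked count was 0 without day 7 of B or day 14 of A or C, and 2 without day 7 of A. From day 14 to day 21 it called 0 (19 unadjusted, DESeq2 0, limma 0), and from day 21 to day 28 it called 0 (9 unadjusted, DESeq2 1, limma 0). A missed threshold here does not show that the days were alike. Any difference among the 5 days was called for 28 miRNAs (83 unadjusted), and for 72 with the block. Without the day 1 library of preparation A 15 were called, and 41 with the block, which called 38 without day 1 of B.

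**Figure D3:**
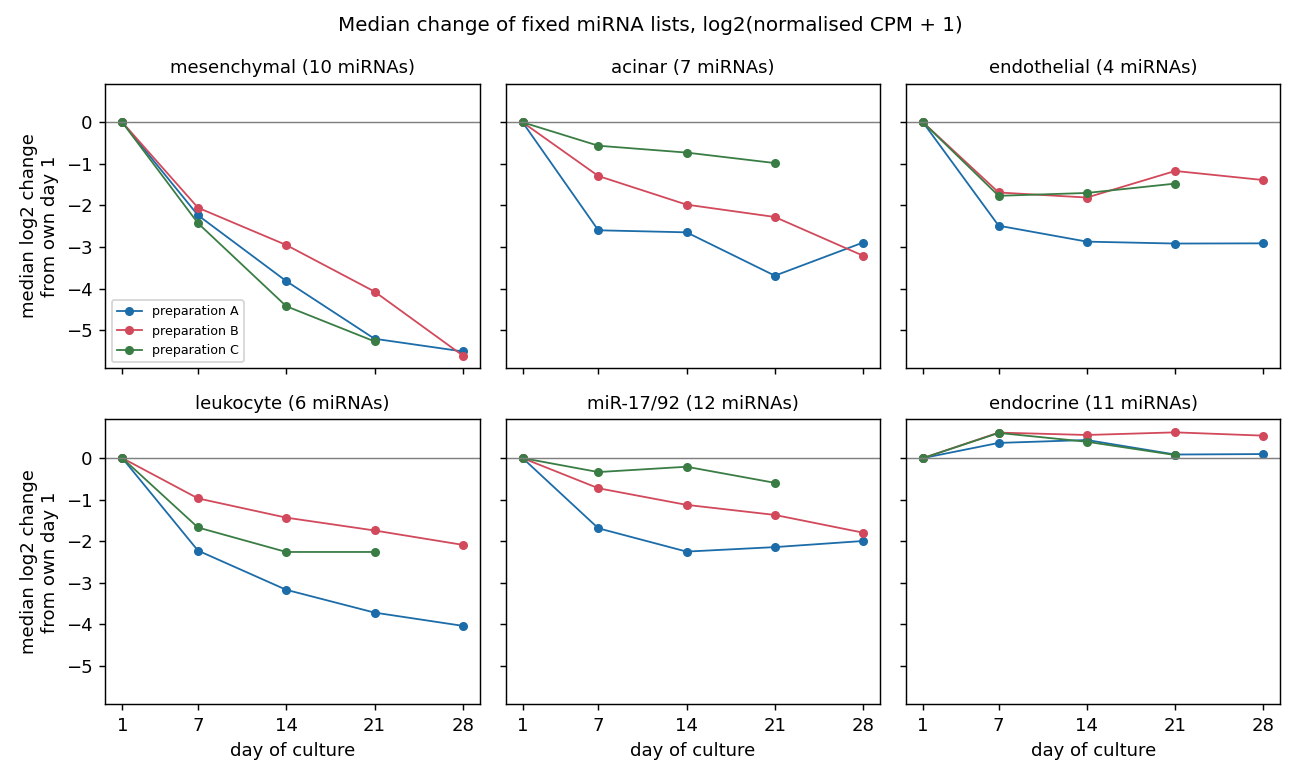
Median log2 change of list members from the same preparation's own day 1 (normalised CPM + 1) against day of culture, with 1 line per preparation for 6 lists. On the last day the mesenchymal medians of A, B and C were -5.51, -5.61 and -5.27, and the endocrine ones 0.10, 0.54 and 0.07.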

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

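Of the tests in this part, those on reads taken up by miR-375-3p and on loss of non-endocrine cells were chosen after the results were seen. The test of the miR-17/92 list was chosen after the GC trend was seen.

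The change over culture differed between the preparations for 1 of 783 miRNAs, the low-abundance joined entry of miR-4520-2-3p and miR-4520-3p. Its slopes over log2 day were 0.06, 0.24 and -1.93 in A, B and C (interaction test, edgeR, adjusted p = 0.0423, 1 of 3 preparations falling, mean CPM 2.01), and 92 miRNAs had an unadjusted p below 0.05. Without the day 1 library of preparation A 3 were called, this entry among them (1 of 1 kept, adjusted p = 0.0409), so that library moves the count. The falling slope of this entry is that of C, so leaving out a library of A could hardly end its call. With 1 such entry, the test does not decide whether that library stands apart. No other explanation was tested. On simulated data this interaction test recovered 18.7% of miRNAs given a slope of 1 in A alone, and called 2 unchanged ones. The low number of calls therefore does not show that the preparations changed alike.

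The 21 members of the mesenchymal, endothelial and acinar lists, pooled, had a median of -4.70 at day 28, or -4.88 with the block. All 10 mesenchymal members lay at -5.79 or lower, and the pooled median without the block equalled the largest acinar fall (-4.70). It therefore mainly reflects the mesenchymal list and does not describe the other lists. This pooled fall was weighed against 3 explanations. The endothelial list on its own was not called by camera at day 28 (median -2.01, adjusted p = 0.205, and 0.0588 with the block), while fry called it lower (adjusted p = 0.00374). Removing the fitted line on hairpin-arm GC, its average level included, left a median of -4.41 (-4.54 with the block). This argues against a loss of low-GC small RNA in extraction as the whole cause of the pooled fall. By list, the medians went from -6.68 to -6.27 (mesenchymal), -2.01 to -1.64 (endothelial) and -3.07 to -2.61 (acinar). A rise in reads taken up by miR-375-3p moves all others alike, by -1.10, -1.56 and -0.93 on the last day in A, B and C. The members' medians on library size alone were -5.19, -5.16 and -2.53 (a difference of -1.59 in C, the smallest). For the 21 members pooled, this argues against it as the whole cause. The lists were not weighed singly against this uptake. Their medians in C were -5.27 (mesenchymal), -1.47 (endothelial) and -0.98 (acinar) on the TMM scale. That scale differs from the library size used for the uptake, so these medians cannot be set against it. Loss of non-endocrine cells in culture was tested outside these lists, where the leukocyte median lay below 0 on the last day in 3 of 3 preparations (-4.04, -2.09 and -2.26), too few preparations to decide. Cell loss and a lower expression per cell cannot be told apart and stay open, as does an untested library batch that followed the day of culture, and of the 4 endothelial miRNAs miR-139-5p and miR-139-3p were not called and 2 of 4 were lower in B and in C.

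Outside the cell-type lists, miRNAs with low-GC hairpin arms tended to be lower at day 28: the Spearman correlation of log2 fold change with GC across 229 miRNAs was 0.332 (0.325 with the block, and 0.249, 0.363 and 0.192 in A, B and C; permutation p = 1e-04, the smallest the permutations can give). It was 0.244, 0.284 and 0.283 at days 7, 14 and 21 against day 1, and miRNAs are not independent replicates. The trend is consistent with a loss of low-GC small RNA in Trizol extraction, as could follow a lower input of cells, but input amounts were not analysed here and a biological trend was not tested. The miR-17/92 list has a low median GC (45.7%). Its median was -2.19 before and -1.64 after the fitted line on GC was removed (-2.75 and -1.90 with the block). The remaining fall argues against low GC as the whole cause. That line includes the average change of the miRNAs fitted, so the shift in the median is not all due to GC. The endocrine list, at a median GC of 49.1%, also moved, from 0.35 to 0.82. Lists with a lower median GC than miR-17/92 differed. The 14q32 list (43.8%) went from -0.62 to -0.13 (-0.84 to -0.14 with the block). The miR-29 list (40%) went from -0.95 to 0.09 (-1.18 to 0.01 with the block). These day 28 falls cannot be told apart from the GC trend. The acinar (45.5%) and leukocyte (45.6%) lists went from -3.07 to -2.61 and from -7.43 to -6.76. For miR-17/92, fewer dividing cells were not tested and stay open.

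Chance assignment of libraries to days was tested by regrouping. For any difference among days, 1 of 100 random assignments, the real one included, gave as many calls as the real one (28, highest other 10). This shuffle ignored the pairing of libraries by preparation. With days permuted within preparations and the block, 2 of 100 did (72, highest other 87). Both shares were below 0.05, which argues against chance for these counts. With 100 draws the second share is imprecise, and 1 regrouping called more than the real one, so chance is not excluded. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real value and the highest other were 4 and 0 at day 7, 19 and 0 at day 14, 33 and 0 at day 21 against day 1, and 3 and 0 at day 21 against day 7, each reached by 1 split. At day 14 against day 7 and day 21 against day 14 both were 0, reached by all 10. Among the 4 splits that part every pair, the blocked counts were 23, 79, 104, 8, 1 and 0 in that order for the real split, and at most 0 for the others.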

How the results depend on the processing

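Tests added after the data were seen are zeros as 1 read, without miR-375-3p, without preparation A (with and without the block) and the block with RLE scaling or library size only. Among named miRNAs and single lists, 7555 values under an alternative stayed on their side of the threshold, 468 kept direction and came to pass it, 239 kept direction and no longer passed, and 1 was called against its direction: let-7a-5p/7c-5p at day 28, at -1.15 with the block and library size only. Of the 7555, 569 changed sign, all uncalled in both fits. The 7555 include values that were uncalled in both fits, so these counts do not give the share of calls that was kept. Of the 239, single miRNAs lost 109 calls without 1 library, 33 with only the 2 groups, 22 with library size only, 20 without preparation A, 11 with limma, 4 each with no filter and with the block and without preparation A, 3 with the block and library size only and 2 without miR-375-3p, and the others were lists. The falls of miR-143-3p, miR-145-5p and miR-199a-5p at day 21 and day 28 against day 1 kept their call in every alternative run. Depth limits miRNAs near 3 counts, worth up to 0.440 CPM. The cause of the moves below was not tested, except where fewer samples or miRNAs entered.

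With preparation as a replicate block (the pairing given by the labels), calls were 72 for any day, 23, 79, 104 and 118 for days 7, 14, 21 and 28 against day 1, 8 for day 21 against day 7 and 1 for day 14 against day 7, and 9 and 8 lists at day 7 and day 21. It also changed calls of single listed miRNAs that the report gives in part. Examples it leaves out at days 14 and 21 were falls of miR-31-5p (-2.42 and -2.43, adjusted p = 0.0156 and 0.0139), miR-203a-3p (-1.29 and -1.72, 0.0485 and 0.0111) and miR-451a (-3.95 and -3.98, 0.0329 and 0.0346), and at day 21 a rise of miR-342-3p (1.73, 0.0111), which was not called with library size only as well (0.0515). With the block and without preparation A miR-203a-3p at day 14, miR-451a at both days and miR-342-3p were not called (0.301, 0.348, 0.353 and 0.0681). With block and RLE, in the same order, they were 77, 18, 81, 100, 122, 8 and 1; with block and library size only 110, 36, 80, 122 and 171, and 13 for day 21 against day 7. With block and without preparation A they were 9, 30, 54 and 127 for the 4 days against day 1 and 1 for day 14 against day 7.

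Without preparation A and without block, calls were 18 for any day, 7 at day 7, 14 at day 21, 87 at day 28, 1 for day 14 against day 7, and 1 list at day 21 against day 7. DESeq2 gave 67 for any day, 26, 59, 82 and 92 against day 1, 10 for day 21 and 2 for day 14 against day 7, and 1 for day 28 against day 21. limma gave 19 at day 7 and 47 at day 14. Zeros as 1 read, which are the reads recovered from the RPM, gave 49 for any day and 8, 46, 54 and 54 against day 1. No filter gave 90, then 42, 70, 83 and 83 against day 1, 20 and 5 for day 21 and day 14 against day 7, 1 for day 21 against day 14 and 3 for day 28 against day 21. The stricter filter gave 5 for day 21 against day 7, and removal of miR-375-3p 1 at day 7. With only the 2 groups compared, and so fewer samples, calls were 0, 10, 15 and 16 against day 1 and 1 for day 21 against day 7. With an estimated correlation 1, 2, 2 and 1 lists were called against day 1 and 1 at day 21 against day 7, and with fry 9 at day 28 and 1 at day 21 against day 7. The 9 included the endothelial, gastrointestinal and hepatic epithelial, miR-30 and NF-kB induced lists, which camera with the preset correlation did not call without the block.

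Leaving out 1 library in turn, without the block, gave 15 to 41 calls for any day, 0 to 2 at day 7, 7 to 22 at day 14, 15 to 33 at day 21 and 8 to 41 at day 28 against day 1. The ranges were 0 to 5 for day 21 and 0 to 1 for day 14 against day 7, 0 to 0 for day 21 against day 14 and 0 to 2 for day 28 against day 21. List counts ran from 5 to 7, 4 to 6, 4 to 5 and 4 to 6 against day 1 and 1 to 3 at day 21 against day 7. Libraries that moved a count by over 1.5 times were day 1 of A for any day (15) and for day 21 (21), each of the 6 at day 7 (1, 2 and 1 without day 1 of A, B and C, and 2, 0 and 0 without day 7), each day 14 library (7, 9 and 8), day 21 of A (15) and of C (19), day 28 of B (8), and, at day 21 against day 7, day 7 of A (5) and day 21 of C (0), with day 21 of A for its lists (1). At day 14 against day 7, day 7 of A gave 1, and at day 28 against day 21, day 28 of A gave 2. With the block they were day 1 of A and B for any day (41 and 38), each of the 6 at day 7 (10, 14 and 47 without day 1 of A, B and C, and 14, 9 and 8 without day 7), at day 14 day 1 of A and B (43 and 51) and day 14 of A and B (25 and 27), at day 21 day 1 of A and B (63 and 57) and each day 21 library (56, 51 and 64), at day 28 day 1 of A (73) and day 28 of B (47), at day 14 against day 7 day 7 of A (2) and of B (0) and day 14 of A and C (both 0), and at day 28 against day 21 day 28 of A (2). A list call ended without 1 library for 14q32 at day 14 (day 14 of B, day 1 or 14 of C; adjusted p = 0.0585 to 0.116) and day 28 (day 28 of B, 0.223), endothelial at day 14 (either day of A or C, 0.0511 to 0.0833), and leukocyte at day 28 (day 28 of A, 0.0504) and at day 21 against day 7 (either day of A, 0.0709 and 0.195). Without preparation A as a whole it ended for endothelial at day 14 (0.0537) and for leukocyte at day 28 (0.147) and at day 21 against day 7 (0.164), and with fry for 14q32 at day 14 (0.117) and leukocyte at day 21 against day 7 (0.0725). A day 28 group of 1 library is assumed to vary like the other groups.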

Other observations

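No test in this part was chosen after its result was seen, except the block with library size only or without preparation A. miR-100-5p was picked after its values were seen.

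Among abundant miRNAs outside the cell-type lists, miR-99b-5p was higher in the blocked fit at day 14, day 21 and day 28 against day 1, by 1.51, 1.51 and 1.796 ± 0.43 at day 28 (edgeR, adjusted p = 0.0292, 0.0242 and 0.0149, in every preparation). Without the block it was not called at day 28 (adjusted p = 0.496), nor on any of these days with the block and library size only (0.78, 0.74 and 0.83, adjusted p = 0.0990, 0.0898 and 0.0778), nor with the block and without preparation A at day 14 and day 21 (adjusted p = 0.197 and 0.0518). Its share of reads was 1.40% ± 0.816 (SD, n = 3) on day 1 and 2.04% ± 1.40 (n = 2) on day 28. miR-26a-5p held 9.11% ± 1.40 of reads on day 1 and 4.76% ± 2.62 on day 28, and after TMM scaling was at -0.26 ± 0.42 (adjusted p = 0.793, 1 of 2 preparations lower). let-7f-5p, let-7g-5p and miR-26b-5p were not called at day 28 with or without the block, at 0.17 ± 0.43, -0.07 ± 0.35 and -0.65 ± 0.36 without it. On library size alone and with the block, miR-26a-5p, let-7g-5p and miR-26b-5p were called lower (-1.07, -1.19 and -1.69, adjusted p = 0.0418, 0.0266 and 0.0102), and let-7f-5p was at -0.87 (adjusted p = 0.0943). miR-877-5p, called higher at day 7 with the block, though not with library size only as well (adjusted p = 0.0519), was also higher there at day 28, by 2.25 ± 0.48 (adjusted p = 0.00840, both preparations, 0.194 without the block). From day 7 to day 21 the 1 blocked fall outside the mesenchymal list was miR-100-5p, by 1.63 ± 0.35 (adjusted p = 0.0470, in all 3 preparations).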
